A study of Danio rerio with 4 samples.

How the data were processed

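RNA of male zebrafish skin was sequenced in 4 libraries, made from total RNA with an Illumina multiplex kit for mRNA, per the labels' protocols. The groups were 5 months (n = 1), 24 months (n = 2) and 30 months (n = 1), taken from the labels, with replicates numbered within a group. CASAVA 1.7, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build GRCz10 are named, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here.

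The deposited table of counts holds whole reads per gene for 32105 Ensembl genes in the 4 libraries, and it was the basis of every main result. A second deposited table, named for RPKM, was treated as a score, because its values do not follow the counts with 1 factor per library. Among 10718 genes the factor between counts and these values depended on the row number with a period of 24 rows. The library totals used ranged from 0.391 to 2.05 times the library's own total, so this table served only as an alternative unit, as deposited and after the totals were corrected.

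Symbols were taken from a table of gene names for 26269 genes, and 4301 genes share their symbol with another gene and are given with their identifier. Many symbols follow human names, so a zebrafish gene may appear under the name of its human counterpart. No coordinates are given, because the annotation at hand belongs to another build (GRCz12tu) and served only for synonyms. Reads of near-identical paralogues (globins, myosins, parvalbumins, keratins, MHC genes) could be split or lost in counting, and reads of overlapping or antisense genes cannot be told apart without the strand setting, so single members of such families are uncertain.

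Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr by group (21535 genes kept), glmQLFit with its default settings and glmQLFTest, and Benjamini-Hochberg adjustment at 0.05. A model of group means gave 24 against 5 months and 30 against 24 months, and a model of age in months gave a slope, printed per 10 months. The labels state no model. In the model of group means only the 24-month pair gives residual spread (1 degree of freedom), and the lone libraries are assumed to vary like that pair. The model of age has 2 residual degrees of freedom, which also take in departures of the ages from a line. The TMM factors were 1.14, 1.15, 0.817 and 0.932 for 5 months, 24 months replicates 1 and 2 and 30 months. Library totals alone shifted the median of all genes by −0.20 between 24 and 5 months, −0.09 between 30 and 24 months and −0.11 per 10 months, so directions are relative to the TMM scaling. For 30 against 5 months, and between single libraries, log2 differences of TMM-scaled CPM with a prior count of 2 were taken without a test, and genes were counted at 2-fold among those with a mean of at least 5 CPM. Where a group had 0 counts, a fold is a bound against 3 counts over the group, and with 1 to 3 counts an exact 95% counting interval is given.

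The tests, the gene lists and the rule for named genes were fixed before the data were examined. Named genes carry a symbol that is not a clone-style name and have a mean of at least 5 CPM. Between 24 and 5 months they are the 12 largest rises and 12 largest falls among called genes with both replicates on the same side, filled up by the smallest unadjusted p. Between 30 and 24 months they are 10 and 10, with the 30-month library outside the range of the pair. For the trend they are the 10 and 10 smallest p-values with libraries in order of age, and for 30 against 5 months the 12 and 12 largest differences beyond that of the 24-month pair. For each list they are up to 4 members with the smallest p and the most abundant member. The genes lgals4, SAMHD1 and DHCR7 lie outside this rule and were chosen after their values were seen. The rule takes tfa, c3a.1, mxc, ACOD1 and enam for their lists, but they were picked from those members for a separate account after their values were seen.

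The 35 lists cover dermal matrix, basement membrane, matrix proteases, epidermal keratins and junctions, melanophore, iridophore, xanthophore, macrophage, neutrophil, T and NK cell, B cell, antigen presentation, interferon response, inflammation and complement, immediate early, heat shock and chaperones, cell cycle, senescence and p53, oxidative phosphorylation, mitochondrial transcripts, ribosomal proteins, proteasome, lysosome and autophagy, antioxidant defence, lipid metabolism and adipocyte, skeletal muscle, bone and scale, erythrocyte, ionocyte, mucous and secretory cells, nerve and Schwann cell, endothelium and mural cell, internal organ and germline, and circadian clock. Names were matched by symbol, synonym or human-style symbol, and 1553 genes belong to 1 list and 41 to 2. The lists were tested with camera of limma 3.58.1 at its preset inter-gene correlation, again with an estimated correlation, and with fry. Medians were ranked among 10000 random lists matched on mean expression in 10 bins. Lists of testis structure, kidney tubule and fibroblast genes were drawn up after germ cell, renal and collagen genes had been seen.

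The methods were tested on simulated counts with 200 changed genes. Between 24 and 5 months (20801 genes) 0% of 4-fold and 16-fold and 16.7% of 64-fold changes were recovered, between 30 and 24 months (20694 genes) 0%, 1.49% and 22.7%, and for the trend (20737 genes) 0%, 0% and 13.6%. Unchanged genes called numbered 0, 0 and 1. Genes were simulated independently, all at the common dispersion of the group fit (0.586), which matches what the fit assumes. These counts therefore cannot give the rate of false calls in the data. A simulated list shifted 2-fold between 24 and 5 months had a camera adjusted p of 7.90e-05 at the preset and 0.999 with an estimated correlation, and 0 other lists were called. Its genes were independent too, as the preset assumes. This simulation therefore cannot show how often the preset calls unchanged lists of correlated genes. Unchanged libraries sharing the 5-month library were simulated 20 times.

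Alternatives fixed before the data were examined were size factors of DESeq2 1.42.0, library totals alone, other floors on low counts, DESeq2, limma-voom, a 1.5-fold glmTreat test, limma on the deposited scores, other prior counts, other groupings, removal of muscle, blood, ribosomal and mitochondrial genes, thinning to the smallest total and leaving out libraries. Chosen after the data were seen were the newer edgeR dispersion setting, removal of other-tissue genes, a 2-fold rule of replicate agreement and corrected scores. Tables and figures were made with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.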

Results

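RNA from the skin of male zebrafish was sequenced at 3 ages, in 4 libraries: 1 from 5 months, 2 from 24 months (replicates 1 and 2) and 1 from 30 months. The libraries of 5 and 30 months carry the strain name AB JxTu, while those of 24 months come from the reporter line AB JxTu Tg(wt1b:GFP), in which sequence of wt1b drives green fluorescent protein, so strain and the age of 24 months cannot be told apart. The total counts were 18211821 at 5 months, 20070292 and 11833498 at 24 months and 20441260 at 30 months, and 24270, 24481, 19409 and 23155 of 32105 genes had at least 1 count. A count of 0 allows up to 0.165, 0.149, 0.254 and 0.147 CPM (counts scaled to a common library total, here before TMM scaling) in these libraries. Such floors cover counting error only. The bounds below use TMM-scaled CPM, in which 3 counts at 30 months are 0.158 CPM. Mitochondrial transcripts took 5.23%, 6.45%, 1.27% and 12.9% of the counts. The labels do not say whether a library came from 1 fish or a pool, or whether the 24-month pair came from different fish. A repeat library of the same RNA is argued against for that pair. In it 5339 of 13182 genes with a mean of at least 5 CPM lay at least 2-fold apart, against 2200 between 5 months and replicate 1. Whether the spread between the pair lies between fish or between pieces of tissue is not known. In the comparisons of groups the p-values rest on that spread alone, averaged across genes, as the prior degrees of freedom were infinite. A gene's own spread between the replicates was thus replaced by that average. In the age trend, with 2 residual degrees of freedom, departures of the ages from a line enter too. The libraries of 5 and 30 months have no replicates. Levels below are CPM after TMM scaling, and fold changes are on the log2 scale.

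The 24-month replicates differed at more genes than 3 of the 5 pairs of libraries of different age. Of 13182 genes with a mean of at least 5 CPM, 5339 lay at least 2-fold apart between replicates 1 and 2, against 2200 between 5 months and replicate 1, 5686 between 5 months and replicate 2, 3559 between 5 and 30 months, 3536 between replicate 1 and 30 months and 5624 between replicate 2 and 30 months. Genes that set the replicates apart included type I collagen, the main fibre of the dermis: COL1A1 stood at 1729 CPM in replicate 1 and 25108 CPM in replicate 2, beside 14839 CPM at 5 months and 2790 CPM at 30 months. The germ cell genes PIWIL1, which guards the germline genome against transposons, and DDX4, the germ plasm helicase Vasa, stood at 216.0 and 147.6 CPM in replicate 1 and at 0 and 0.414 CPM in replicate 2. At 5 months they stood at 237.5 and 116 CPM, and at 30 months both stood at 0.158 CPM. Of the genes with at least 10 CPM in some libraries and at most 0.5 CPM in the rest, 148 were detected in the 5-month library and replicate 1 together, and 15 in the 5-month library alone. Spearman's rho across genes, which are not independent replicates, was 0.738 for the 24-month pair and from 0.704 to 0.854 for the other 5 pairs. A chi-square test of the 2 replicates gave 197 per degree of freedom over 19172 genes, so they are separate libraries.

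**Figure D1:**
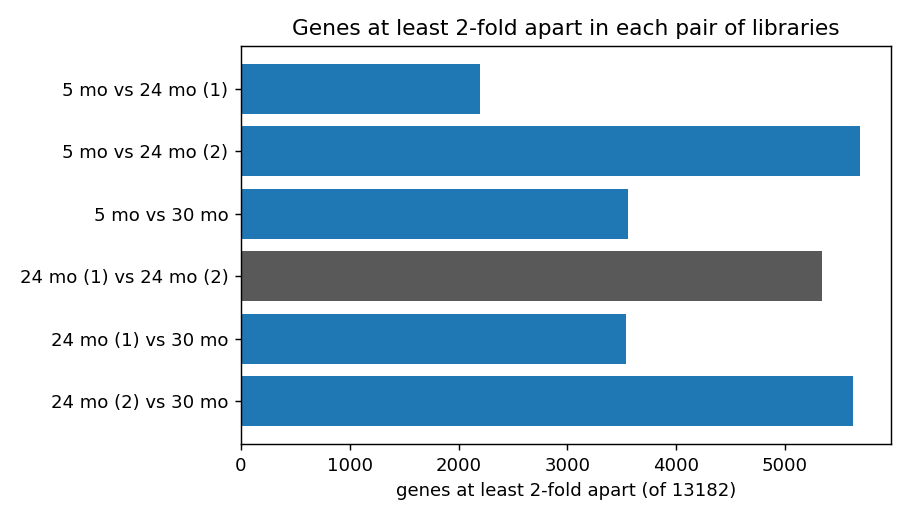
Number of genes at least 2-fold apart (x axis, of 13182 genes with a mean of at least 5 CPM) in each of the 6 pairs of libraries (y axis), with the 24-month replicate pair in grey. The replicate pair, with 5339 genes, lies above the pairs of 5 months with replicate 1 (2200), 5 with 30 months (3559) and replicate 1 with 30 months (3536).

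**Figure D2:**
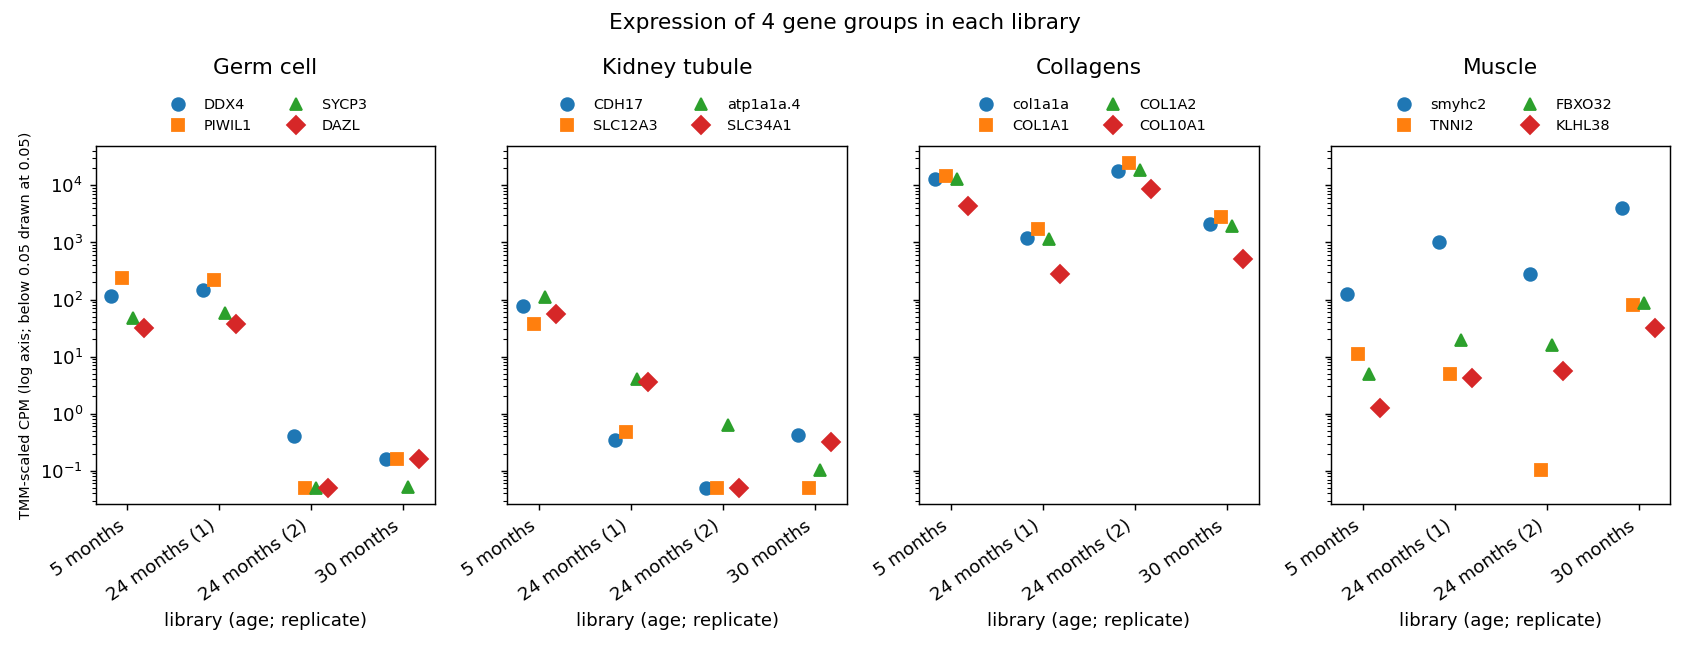
Level of single genes (y axis, TMM-scaled CPM on a log axis, values under the bottom of the scale drawn there) in each of the 4 libraries (x axis), 1 point per gene and library, for germ cell, kidney tubule, collagen and muscle genes. Germ cell genes lie high at 5 months and in 24-month replicate 1, kidney genes at 5 months, and collagens at 5 months and in 24-month replicate 2, where COL1A1 reached 25108 CPM.

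The comparison of 24 with 5 months asks how skin transcripts of old fish differ from those of young adults. The called genes that fell included several renal tubule transporters, a globin and a muscle actin. A kidney tubule list, drawn up after the data were seen, had medians against 5 months of −1.27 and −3.19 in replicates 1 and 2. Its share of counts was not highest at 5 months, at 0.224% against 0.279% and 0.251%. CDH17 (ENSDARG00000005112), a cadherin of kidney and gut epithelia, fell by 8.51 (SE 1.28, edgeR adjusted p = 6.15e-07, n = 1 and 2), from 78.0 CPM to 0.348 and 0 CPM. The sodium-chloride cotransporter SLC12A3 (ENSDARG00000013855) of the distal tubule fell by 7.05 (SE 1.47, adjusted p = 0.00412) from 36.9 CPM to 0.478 and 0 CPM, and the sodium-potassium ATPase subunit atp1a1a.4 fell by 5.55 (SE 1.01, adjusted p = 0.000416) from 112 CPM to 4.00 and 0.621 CPM. The dicarboxylate carrier SLC13A3 fell by 7.56, from 25.8 CPM to 0.217 and 0 CPM, and the organic anion carrier SLC22A8 fell by 5.19, from 44.9 CPM to 1.96 and 0.414 CPM. The phosphate carrier SLC34A1 (ENSDARG00000028824) fell by 4.88, from 55.8 CPM to 3.65 and 0 CPM, and the endocytic receptor CUBN fell by 4.81, from 50.1 CPM to 3.26 and 0.207 CPM. With replicate 1 alone at 24 months the log2 differences of SLC34A1 and CUBN were −3.89 and −3.90, and with replicate 2 alone −8.99 and −7.31. The brush border scaffold pdzk1 had 431 counts at 5 months and 2 in the 24-month libraries together, a ratio of 338 with a 95% counting interval from 93.0 to 2801. Outside this group, the transglutaminase-like tgm1l2 fell by 5.98 (from 52.9 CPM to 1.48 and 0.103 CPM), the osteocalcin-like bglapl by 5.32 (31.7 CPM to 0.478 and 1.14 CPM), the decarboxylase DDC by 4.51 (73.5 CPM to 0.956 and 5.59 CPM), the adult globin hbaa2 by 4.42 (SE 1.01, adjusted p = 0.0161) and the actin ACTA1 (ENSDARG00000055618) by 4.28 (SE 0.86, adjusted p = 0.00295).

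Of the genes that rose, several stood high in 1 replicate only. The cytochrome P450 gene CYP8B1 (ENSDARG00000053068) rose by 5.88 (SE 1.19, adjusted p = 0.00295), from 2.35 CPM to 67.8 and 210 CPM, the lectin gene itln4 by 4.66 (SE 1.12, adjusted p = 0.0339), from 7.44 to 62.1 and 314 CPM, and vopp1a by 6.46 (SE 1.27, adjusted p = 0.00178), from 1.06 to 35.6 and 152 CPM. At 30 months CYP8B1 and itln4 stood at 99.3 and 76.3 CPM, but vopp1a at 0.210 CPM. High levels of vopp1a were thus confined to the 24-month libraries, those of the reporter line. The granulin gene grna.1, which myeloid cells express, rose by 5.54 (adjusted p = 0.00578), with 255 CPM in replicate 1 and 4.03 CPM in replicate 2 against 2.78 CPM at 5 months. The 5-lipoxygenase gene alox5b.2 stood likewise at 89.3, 1.14 and 0.576 CPM (adjusted p = 0.0223). The interferon-induced ifi44a6 had 2 counts at 5 months and 1358 at 24 months, a ratio of 433 with a counting interval from 120 to 3577 and with 58.7 CPM in replicate 1 against 0.827 CPM in replicate 2. The immunoglobulin heavy chain gene ighm was called higher (adjusted p = 0.00841) although replicate 2, at 2.07 CPM, lay below the 3.74 CPM of 5 months. The MHC class I gene mhc1uba, at 5.90 CPM against 13.2 and 367.9 CPM, did not pass (adjusted p = 0.124), nor did grna.2, the nitric oxide synthase NOS2 (ENSDARG00000031976), cry5, ttbk1b or CYP24A1.

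In all, 27 of 21535 tested genes passed at an adjusted p of 0.05, 9 higher and 18 lower at 24 months, and 438 had an unadjusted p under 0.05. Both replicates lay at least 2-fold on the same side of the 5-month library for 5 of the higher and all 18 of the lower genes. Of the lower genes, 17 stood at least 4 times higher in the 5-month library than in each of the others, and 6 of the 27 genes stood at least 4 times higher in replicate 1 than in each of the others. The count was 43 with DESeq2, where 24 were higher and 19 lower, 3 with limma-voom, and 0 with library totals alone, with a floor of 5 CPM or with the newer edgeR dispersion setting. Each SE and p-value takes the spread of the 24-month pair, averaged across genes, as that of the lone 5-month library.

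Of 35 gene lists, camera with a preset correlation called 18 between 24 and 5 months, 11 higher and 7 lower. For each of the 18 lists the adjusted p was 0.839 with an estimated correlation, so no call held there. That setting also missed a simulated list shifted 2-fold between 24 and 5 months (camera adjusted p = 0.999). Its failures here and below therefore cannot tell changed lists from unchanged ones. The correlations it estimated were 0.60 for ribosomal protein, 0.82 for cell cycle, 0.50 for skeletal muscle and 1 for mitochondrial transcripts. The preset takes the genes of a list as nearly independent, so its p-values here and below do not measure spread between fish. Fry called no list, with a lowest adjusted p of 0.875 here, 0.987 between 30 and 24 months and 0.797 on the age trend. Of 81 ribosomal protein genes, 79 were higher (median 0.94, adjusted p = 3.33e-18), with RPS28 at 123.6 CPM against 579.5 and 769.5 CPM, and no single member passed the gene test, over all genes or adjusted over the list alone. Macrophage markers were higher in 37 of 42 members (median 1.44, adjusted p = 9.05e-12), with 1 called over all genes and 2 adjusted over the list alone, and the medians against 5 months were 1.62 for replicate 1 and 0.41 for replicate 2. The class II chaperone gene cd74a stood at 632.8 CPM against 1819.9 and 3821 CPM. Antigen presentation genes (31 of 34 higher, median 0.81), T and NK cell genes (35 of 46, median 1.19) and B cell genes (23 of 28, median 0.82) had adjusted p-values of 3.09e-06, 0.000144 and 0.000349, and their counts adjusted over the list alone were 1, 0 and 1 beside 0, 0 and 1 over all genes. Epidermal junction genes were higher in 36 of 42 members (median 0.77), among them the desmosomal cadherin dsc2l, at 145.0 CPM against 965 and 1453 CPM. Immediate early genes, which respond within minutes to handling, were higher in 39 of 49 members, with a median of 1.44 in replicate 2 and 0.07 in replicate 1. In replicates 1 and 2 the medians were 0.57 and 1.22 for ribosomal protein, 0.74 and 0.37 for antigen presentation, 0.93 and 0.34 for T and NK cell, 0.80 and 0.22 for B cell and 0.34 and 1.11 for epidermal junction genes.

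The lower lists were skeletal muscle, cell cycle, erythrocyte, ionocyte, internal organ and germline, mitochondrial transcripts and dermal matrix, each with an adjusted p of 0.839 with an estimated correlation. Of 69 skeletal muscle genes 62 were lower (median −1.42, adjusted p = 7.76e-22), 1 called over all genes and 8 adjusted over the list alone, and the parvalbumin gene pvalb1 went from 2142 CPM to 357 and 23.3 CPM. Cell cycle genes were lower in 82 of 85 members (median −1.12), none passing either way, and the medians were −0.43 for replicate 1 and −2.68 for replicate 2. The testis list, drawn up after the data were seen, moved with them, with medians of −0.15 for replicate 1 and −5.91 for replicate 2. Erythrocyte genes (20 of 24 lower, median −1.29) had 1 call over all genes and 3 adjusted over the list alone, and ionocyte genes (24 of 37, median −1.06) had 2 and 3. In replicates 1 and 2 the medians were −1.07 and −2.03 for skeletal muscle, −0.80 and −1.95 for erythrocyte and −0.58 and −1.61 for ionocyte genes. The internal organ and germline list had a median of −0.74, from −0.10 in replicate 1 and −4.05 in replicate 2. Mitochondrial transcripts (median −0.43) and dermal matrix genes (median −0.37) were lower too, but the median was 0.16 for mitochondrial transcripts in replicate 1 and 0.11 for dermal matrix in replicate 2. Among the higher lists, inflammation and complement (median 0.70) and interferon response (0.42) had medians of −0.28 and −0.29 in replicate 2, the circadian clock list (0.32) had −0.11 in replicate 1, and the senescence and p53 list (0.28) had 0.10 and 0.16 in replicates 1 and 2. Adjusted over the list alone, 1 gene of inflammation and complement and 1 of the circadian clock list passed, beside 0 over all genes. With an estimated correlation each of these 4 higher lists had an adjusted p of 0.839.

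The other 17 lists did not pass (adjusted p from 0.0782 to 0.993): basement membrane, matrix proteases, epidermal keratins, melanophore, iridophore, xanthophore, neutrophil, heat shock and chaperones, oxidative phosphorylation, proteasome, lysosome and autophagy, antioxidant defence, lipid metabolism and adipocyte, bone and scale, mucous and secretory cells, nerve and Schwann cell, and endothelium and mural cell. Within them the laminin chain gene lamb3, which anchors the epidermis, stood at 130.5 CPM at 5 months, at 715 CPM in replicate 1 and at 2375 CPM in replicate 2, without passing the gene test. For 10 of these 17 lists the median, the mean and the direction of the test differed in sign.

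**Figure D3:**
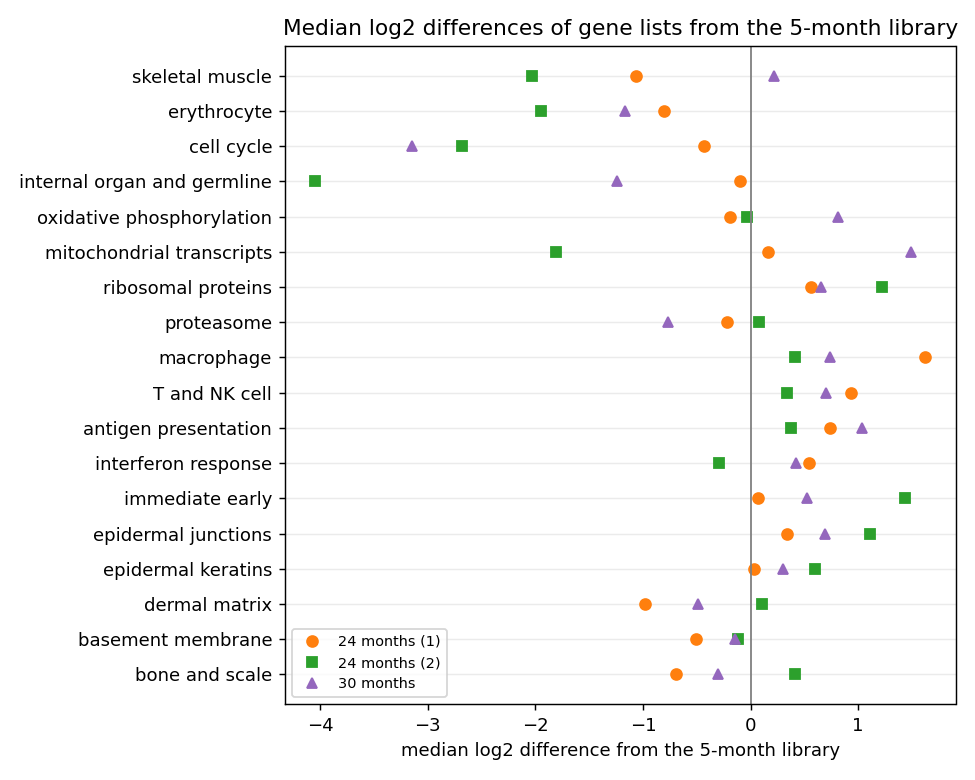
Median over the genes of a list of the log2 difference from the 5-month library (x axis) for 18 lists (y axis), with 1 point for each 24-month replicate and for 30 months. The replicates lie far apart for internal organ and germline genes (−0.10 and −4.05), cell cycle genes (−0.43 and −2.68) and mitochondrial transcripts (0.16 and −1.81).

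The comparison of 30 with 24 months follows skin within old age. Genes of the striated muscle sarcomere rose from 24 to 30 months. The skeletal muscle list, a list of other tissue, took 8.10% of counts at 5 months and 6.53% at 30 months. In replicates 1 and 2 of 24 months its share was 4.27% and 2.14%. Between 30 and 5 months its median was 0.22, with 24 of 69 members at least 2-fold higher and 20 at least 2-fold lower. Whether the libraries held different amounts of muscle was not tested, so these rises cannot be ascribed to age within skin. The troponin genes TNNI2 (ENSDARG00000005841) and tnnc2.1 rose by 4.91 (SE 1.04, edgeR adjusted p = 0.00185, n = 1 and 2) and 4.21 (SE 0.90, adjusted p = 0.00194), from 5.00 and 0.103 CPM to 78.9 CPM and from 12.1 and 2.38 CPM to 134.9 CPM. The myosin genes MYH6 (ENSDARG00000079564), myh7bb and MYL2 (ENSDARG00000104722) rose by 4.47, 3.87 and 3.85, to 52.5, 105.1 and 68.2 CPM from 4.39, 11.3 and 8.86 CPM in replicate 1 and 0.207, 2.90 and 0.414 CPM in replicate 2. Without replicate 1 the log2 differences of TNNI2, MYH6 and MYL2 were 8.53, 7.37 and 7.03, and without replicate 2 they were 3.95, 3.55 and 2.93. The actin gene actc1a rose by 3.84, and the myosin-binding genes MYBPC2 and MYBPC1 rose by 3.49 and 3.36 (adjusted p = 0.0322 and 0.0196), the latter from 36.5 and 34.3 CPM to 364.6 CPM. Other rises were the cadherin gene cdh31 (4.97), HHATL (ENSDARG00000005139, 3.65), the nuclear GTPase gene nuggc.3 (3.53, from 3.00 and 23.3 CPM to 151 CPM) and cpt1ab, which carries fatty acids into mitochondria (3.17, adjusted p = 0.0363).

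The called genes with the largest falls included the MHC class II genes mhc2dgb and mhc2dga and germ cell and testis transcripts, with zero counts at 30 months in many. The antigen presentation list as a whole did not fall, with 20 of 34 members higher (median 0.14, camera adjusted p = 0.515) and 1 called lower. The MHC class II gene mhc2dgb was at least 271-fold lower at 30 months (adjusted p = 1.19e-07), at 0 CPM against 0.348 and 143 CPM, and mhc2dga was at least 42.3-fold lower, on 3 counts in replicate 1 and 215 in replicate 2. Without replicate 2 the log2 differences of mhc2dgb and mhc2dga were −2.05 and −1.13, so both bounds rest on replicate 2. STAR, which brings cholesterol to steroid synthesis, was at least 163-fold lower, the testis genes ADAD1 and topaz1 at least 110-fold and 98.1-fold, the radial spoke gene LRRC23 at least 64.9-fold and the glutamate carrier gene SLC1A1 at least 90.9-fold. These bounds set 3 counts over the 30-month library. DDX4 fell from 3400 counts to 3, a ratio of 660 with a counting interval from 226 to 3204. In STAR, ADAD1, topaz1, LRRC23 and DDX4 replicate 2 lay below 0.5 CPM as well, and without replicate 1 their log2 differences were −2.25, −1.52, −2.25, −0.95 and −0.97. Both 24-month replicates stood high for fabp1b.2, a fatty acid binding protein gene, which fell by 9.57 (SE 1.46, adjusted p = 3.71e-07) from 162 and 166.5 CPM to 0.210 CPM, and for vopp1a, which fell by 8.76. The latter stood at 35.6 and 152 CPM in them, and at 1.06 and 0.210 CPM at 5 and 30 months.

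In all, 147 of 21535 genes passed, 28 higher and 119 lower at 30 months, and 1024 had an unadjusted p under 0.05. The 30-month library lay at least 2-fold outside the range of the pair for all 28 higher and for 32 of the 119 lower genes. Of the lower genes, 102 stood at least 4 times higher in the 5-month library and replicate 1 than in either other library. The count was 77 with DESeq2, where 17 were higher and 60 lower, 7 with limma-voom, 2 with library totals alone and 1 with a floor of 5 CPM or the newer edgeR dispersion setting. Without the genes of the muscle, erythrocyte, internal organ and germline, testis and kidney lists, chosen after the data were seen, it was 116. This removal left 21270 genes, while 1780 tested genes stood at least 4 times higher in the 5-month library and replicate 1 than in the others. It thus could not take out that pattern, and 116 does not show how many calls are free of other tissue.

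Camera with a preset correlation called 6 of the 35 lists between 30 and 24 months, and with an estimated correlation the adjusted p was 0.998 for all 6. Skeletal muscle genes were higher in 57 of 69 members (median 1.65, adjusted p = 7.98e-25), 5 of them called over all genes and 13 adjusted over the list alone. All 13 mitochondrial transcripts were higher (median 2.02), by 3.26 against replicate 2 and 1.38 against replicate 1, and MT-CO1 stood at 49762 CPM against 21497 and 4942 CPM. Nuclear genes of oxidative phosphorylation were higher in 79 of 90 members (median 0.97, adjusted p = 3.56e-14), among them COX6A1 (ENSDARG00000054588) at 405.8 CPM against 90.4 and 124.7 CPM. Cell cycle genes were lower in 83 of 85 members (median −2.01, −0.45 against replicate 2 and −2.71 against replicate 1), proteasome genes in 39 of 41 (median −0.62) and B cell genes in 22 of 28 (median −1.23, 0.01 against replicate 2), the last with 1 member adjusted over the list alone. The 2 libraries with the higher cell cycle levels, 5 months and replicate 1, were those with testis transcripts, and the testis list had a median of −5.18 in replicate 2 against replicate 1. The 4 lists other than muscle and B cell had no member called either way. The other 29 lists did not pass (adjusted p from 0.167 to 0.995). Among these the internal organ and germline list (median −0.92) held 8 genes called lower over all genes and 9 adjusted over the list alone, including PIWIL1, SYCP3, a protein of the meiotic chromosome axis, and sycp2.

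Along age as a number, over all 4 libraries, no gene passed the edgeR test, while 336 had an unadjusted p under 0.05, DESeq2 called 30 and limma-voom 0. Among named genes with libraries in order of age, the rising gene with the smallest p was FBXO32, a ubiquitin ligase of muscle atrophy. It stood at 4.94 CPM at 5 months, 19.8 and 15.8 CPM at 24 months and 86.3 CPM at 30 months, a slope of 1.48 per 10 months. Next among them was mhc1uba (slope 2.99). KLHL38 (ENSDARG00000040278) had 1.25, 4.30, 5.69 and 31.1 CPM in the same order, the chemokine gene ccl44 had 5.95, 25.1, 28.2 and 46.8 CPM, and clca5.1 had 9.65, 33.9, 33.8 and 69.5 CPM. The slow myosin gene smyhc2 had 125.0, 1005, 281 and 4010 CPM. Falling genes under the same limits began with atp1a1a.4 and SLC22A8, given above. The globin HBE1 (ENSDARG00000089087) had 584.8, 105.0, 71.6 and 63.3 CPM, the parvalbumin gene pvalb2 4631, 626, 168 and 79.4 CPM, the tooth and scale phosphoprotein gene scpp7 657, 36.9, 151 and 23.1 CPM, and gch2, a pteridine synthesis gene of yellow pigment cells, 112.0, 19.3, 42.7 and 8.98 CPM. The order of 5 months, both of 24 months, then 30 months was rising for 748 and falling for 893 of 13182 genes, 5.67% and 6.77% against 8.33% by chance. Without the 5-month library 116 genes were called, without replicate 1 372, mostly lower, without replicate 2 0 and without the 30-month library 34. With replicate 1 left out, only the 5-month library carried testis transcripts. Against it the testis list had medians of −5.91 in replicate 2 and −5.49 at 30 months. Those calls therefore cannot tell age from other tissue.

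On the age trend camera with a preset correlation called 19 lists, 12 higher and 7 lower with age. Cell cycle genes were lower in 84 of 85 members (median −0.95 per 10 months, adjusted p = 7.10e-34, but adjusted p = 0.723 with an estimated correlation). MCM2, of the replicative helicase, stood at 125 CPM at 5 months, 59.8 and 45.7 CPM at 24 months and 15.1 CPM at 30 months. Against 5 months the cell cycle medians were −0.43, −2.68 and −3.14 in replicate 1, in replicate 2 and at 30 months, and those of the testis list were −0.15, −5.91 and −5.49. Ribosomal protein (79 of 81, median 0.36), antigen presentation (31 of 34, 0.40) and epidermal junction genes (39 of 42, 0.34) were higher, each with adjusted p = 0.723 with an estimated correlation. Higher lists were also macrophage (37 of 42, 0.49), oxidative phosphorylation (80 of 90, 0.23), inflammation and complement (52 of 66, 0.34), immediate early (39 of 49, 0.29), T and NK cell (36 of 46, 0.47), mitochondrial transcripts (12 of 13, 0.41), lysosome and autophagy (53 of 73, 0.09), interferon response (34 of 51, 0.23) and circadian clock (28 of 45, 0.10). Against 5 months, replicate 2 had medians of −1.81 for mitochondrial transcripts, −0.29 for interferon response and −0.28 for inflammation and complement. Replicate 1 had −0.11 for circadian clock, and oxidative phosphorylation had −0.19 and −0.04 in replicates 1 and 2. With an estimated correlation the adjusted p was from 0.723 to 0.841 for all 19 lists. Lower lists were erythrocyte (20 of 24 lower, median −0.57), internal organ and germline (37 of 52, −0.44), proteasome (37 of 41, −0.18) and dermal matrix (42 of 55, −0.20). Skeletal muscle (37 of 69, −0.15) and ionocyte genes (20 of 37, −0.05) were called lower with members on both sides, and adjusted p = 0.841 and 0.723 with an estimated correlation. No member was called over all genes, and adjusted over the list alone 2 erythrocyte and 3 ionocyte genes were. The other 16 lists did not pass (adjusted p from 0.0807 to 0.933).

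The libraries of 5 and 30 months share the strain name and were set side by side without a test of replicates, since each is a lone library. The genes with the largest differences included several of muscle and the MHC class I gene mhc1uba among those higher at 30 months, while the skeletal muscle list as a whole had 35 of 69 members higher. The log2 difference was 7.78 for mhc1uba (5.90 against 1318 CPM), 6.03 for klhl33, 5.34 for CYP8B1 (ENSDARG00000053068), 5.29 for the myosin gene myhb, 5.00 for smyhc2 and for nuggc.3, 4.83 for igfn1.2, 4.52 for KLHL38 (ENSDARG00000040278), 4.49 for parp14rs2.1, 4.23 for vwa10.2 and 4.09 for FBXO32. Of the testis list 59 of 67 members and of the kidney list 36 of 53 were at least 2-fold lower. The Leydig cell hormone gene insl3 was at least 421-fold lower, the endocytic receptor gene LRP2 at least 256-fold, dcst1 at least 253-fold, mhc2dgb at least 235-fold and SLC12A3 at least 234-fold. The ratio was 1062 for atp1a1a.4 (294 to 8778), 737 for DDX4 (252 to 3577) and 1039 for PIWIL2 (186 to 41060). The log2 difference was −8.87 for hydin and −8.39 for dnah9, both of the ciliary axoneme. Of 13182 genes 3559 lay at least 2-fold apart, 1614 higher and 1945 lower at 30 months, or 905 higher and 2688 lower with library totals alone and 895 higher and 700 lower at a floor of 20 CPM. The edgeR contrast of these libraries, an alternative that takes its spread from the 24-month pair, called 8 higher and 199 lower.

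Of the 35 lists, the cell cycle list stood furthest from 5 months, with 0 of 85 members higher, 79 at least 2-fold lower and a median of −3.14, below all 10000 random lists matched on mean expression. The testis list, whose transcripts the 5-month library and replicate 1 carry, had a median of −5.49, and in replicate 1 the cell cycle median was −0.43. The mitochondrial (1.49), antigen presentation (1.04), oxidative phosphorylation (0.81, 82 of 90 members higher), macrophage (0.73), T and NK cell (0.70), epidermal junction (0.69) and ribosomal protein (0.66) lists had medians above at least 99.9% of such lists. Internal organ and germline (−1.24), erythrocyte (−1.17), proteasome (−0.77), dermal matrix (−0.49) and heat shock and chaperone genes (−0.29) had medians below at least 99.9%. Replicate 2 against replicate 1, of equal age, gave such ranks too. There cell cycle, macrophage, mitochondrial and internal organ and germline lists ranked at percentile 0, antigen presentation at 0.22 and dermal matrix at 99.97. Less extreme were heat shock (3.62), erythrocyte (8.09), oxidative phosphorylation (21.3), proteasome (26.7), T and NK cell (52.35), ribosomal protein (91.4) and epidermal junction (99.1) lists. A rank alone thus does not show a difference of age. The skeletal muscle list had a median of 0.22, with 24 members at least 2-fold higher and 20 at least 2-fold lower. The lipid metabolism and adipocyte list had a median of 0.13, with 37 of 68 members higher, while its members HMGCS1 and LSS stood at 227 and 17.4 CPM against 2302 and 267.7 CPM at 5 months.

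The differences of 24 and of 30 months from the shared 5-month library had a Pearson correlation of 0.634 across genes, where simulated unchanged libraries gave 0.576 (SD 0.00533, 20 simulations). The covariance was 1.01 against 1.58 simulated, and 63.95% of genes had the same sign against 69.4% simulated. Of 13182 genes, those at least 2-fold higher than at 5 months were 1343 at 24 and 1614 at 30 months, 503 of them at both, and at least 2-fold lower were 2045 and 1945, 1027 of them at both. Independent lists of these sizes share 164 and 302. The simulated lists were longer, at 3124 and 3629 genes higher and 3451 and 3639 lower, and shared 1962 (SD 42.7) and 1700.3 (SD 44.1). The simulated spread was thus wider than the observed, and each SD covers repeats of the simulation only. None of the overlaps, the covariance, the correlation and the same-sign share can therefore tell whether an effect is shared. With no library shared, the correlation was −0.04 between replicate 1 minus 5 months and 30 months minus replicate 2, and 0.43 with the replicates exchanged. In the exchanged case the libraries subtracted, 5 months and replicate 1, were those with testis transcripts. Part of the excess over independent lists may come from the shared library. The genes wt1b and WT1 (ENSDARG00000031420, its paralogue wt1a), given because of the reporter line, stood at 1.15, 7.47, 0 and 0.787 CPM and at 3.17, 3.78, 0.517 and 0 CPM at 5 months, in replicates 1 and 2 and at 30 months. Neither passed a test.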

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

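The newer edgeR dispersion setting, the removal of other-tissue genes, the 2-fold rule of replicate agreement and the corrected scores were chosen after the data were seen. No paired analysis was possible because the labels pair no libraries across ages, and the groups of 5 and 30 months hold 1 library each. The 27 calls between 24 and 5 months were 0 with library totals alone, with a floor of 5 CPM, with 24 and 30 months as 1 group, with the newer dispersion setting and with corrected scores, 43 with DESeq2 (24 higher, 19 lower), 3 with limma-voom and 2 with deposited scores plus 1 or plus 0.1. The 147 calls between 30 and 24 months were 2 with library totals alone, 1 with a floor of 5 CPM and with the newer setting, 77 with DESeq2 (57 shared), 7 with limma-voom, 4 and 3 with deposited scores plus 1 and plus 0.1, 0 with corrected scores and 60 with the rule of replicate agreement. The edgeR fits that made over 20 calls had an infinite prior degree of freedom, while fits at 9.31, 10.26, 14.1 and 5.64 made from 0 to 2. The cause of the other changes was not tested. The age trend called 0 genes with edgeR (336 at an unadjusted p under 0.05) and with limma-voom, 30 with DESeq2, and from 0 to 372 with 1 library left out. The 3559 genes 2-fold apart between 30 and 5 months were 5955 at a floor of 1 CPM (2495 higher, 3460 lower) and 1595 at 20 CPM (895 higher, 700 lower), as other numbers of genes were counted, and 207 in the edgeR contrast (8 higher, 199 lower). Their split of 1614 higher and 1945 lower was 905 and 2688 with library totals alone and 1378 and 2272 with scores plus 1, and that of the replicate pair (2646 and 2693) was 1051 and 3873 with library totals alone. The lists called, 18, 6 and 19 for 24 against 5 months, 30 against 24 months and the trend, were 0 in each with an estimated correlation and 0 with fry. With an estimated correlation a simulated list shifted 2-fold was missed too, so that loss cannot tell whether a list changed.

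Some list medians turned with 1 replicate left out. Without replicate 1 and without replicate 2 they were 0.11 and −0.98 for dermal matrix, −0.29 and 0.54 for interferon response, −0.28 and 0.89 for inflammation and complement, −1.81 and 0.16 for mitochondrial transcripts and 0.65 and −0.11 for circadian clock between 24 and 5 months, and 0.00528 and −1.34 for B cells between 30 and 24 months. Counts without a 24-month replicate had no residual degrees of freedom in the comparisons of groups. Of the alternative values of single lists 261 counted as the same and 101 lost the call. Of those of named genes 227 and 160 did so between 24 and 5 months and 148 and 149 between 30 and 24 months. The same meant direction and side of the threshold, or, where a replicate was left out without a test, direction and a small shift. It also took in a repeat of the main fit (24 and 20 values) and, between 24 and 5 months, genes never called. These counts thus overstate how many calls held. Replicate 2 of 24 months, with 11833498 counts, was the shallowest. Thinning all libraries to that total gave 5331 genes 2-fold apart in the replicate pair against 5339.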

Other observations

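Of the tests below, those on age, on fibroblasts, on bone and scale cells and on the deposited scores were chosen only after the result was seen, the rule for bone and scale cells was changed after a value was seen, and the testis and kidney lists were drawn up after germ cell and renal genes had been seen.

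Single genes outside the lists or picked from them, chosen after their values were seen, stood lowest at 30 months. The galectin gene lgals4 stood at 546.8 CPM at 5 months and 739.8 and 738.7 CPM at 24 months, but at 2.89 CPM at 30 months, a change of −7.997 against 24 months (SE 1.61, edgeR adjusted p = 0.000843). SAMHD1, which degrades deoxynucleotides, stood at 62.0, 50.1 and 268 CPM and then 2.78 CPM (adjusted p = 0.000885), and the enamel matrix gene enam at 203, 27.6 and 334 CPM and then 4.46 CPM (adjusted p = 0.00390). The sterol synthesis gene DHCR7 was lowest at 30 months too, at 66.7 CPM against 494 CPM at 5 months, 221 CPM in replicate 1 and 1022 CPM in replicate 2, without passing (edgeR adjusted p = 0.405).

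Of 4 genes chosen after their values were seen, each stood highest in replicate 1 of 24 months. The transferrin gene tfa had 404 CPM there and 1.24 CPM in replicate 2, beside 53.5 CPM at 5 months and 87.2 CPM at 30 months. At 5 months, in replicates 1 and 2 and at 30 months, the complement gene c3a.1 had 7.39, 129.4, 3.41 and 19.01 CPM, the antiviral mxc 9.75, 179, 2.48 and 11.08 CPM, and ACOD1, which makes itaconate in macrophages, 3.70, 92.3, 2.07 and 3.73 CPM. None of these passed a test between ages. The summed level of the inflammation and complement list was highest at 30 months, at 4625 CPM against 3567 CPM in replicate 1.

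Germ cell transcripts were present at 5 months and in replicate 1 of 24 months, and renal transcripts at 5 months. Age alone is argued against for the germ cell genes, since the replicates of 24 months differed by a median of 8.40 (log2, 6.56 to 10.94 over 9 genes, 7.23 with zero counts at the floor). RNA of testis may be a source: 52 of 67 testis genes outside the germline list, 77.6%, were at least 4 times higher in both libraries than in either other, against 8.27% of all tested genes, and the list median between replicates 2 and 1 was −5.18. RNA of kidney in the 5-month library may be another: 18 of 53 tubule genes, 33.96%, were at least 4 times higher there than in each other library, against 1.88% of all, with a list median of −2.62 between 30 and 5 months. That share lay only just above the limit set for this test. The kidney list's share of counts was not highest at 5 months (0.224%, 0.279%, 0.251% and 0.210%), and how such RNA entered was not tested.

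Type I collagen differed 15.2-fold between the replicates of 24 months, a mean of 3.93 (log2, 3.86 to 4.03 over 3 genes), which argues against age as its whole cause. A larger share of fibroblasts as the whole cause is argued against, since 44 fibroblast markers outside the matrix list had a median of 0.34. Its interval from resampling the markers (0.07 to 0.69) lay under the limit of 0.785 set as a share of the collagen difference. Of the markers 30 of 44 were higher. Markers of 1 pair of libraries are not independent replicates, so the interval covers spread between genes only. The dermal matrix list, which holds type I collagen, had a median of 0.84. A larger share of bone and scale cells stays open: 33 genes of that list had a median of 1.27 (0.914 to 1.60 by the same resampling), with 27 higher, between the bounds set. The full fibroblast list had a median of 0.44 between 30 and 5 months.

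The deposited RPKM values did not follow the counts. Library totals recycled down the rows may be the cause: within rows of the same remainder modulo 24 the log2 factor had an SD of at most 0.000259, and 1 cyclic vector of 24 totals held all 4 library totals. Other gene lengths are argued against, because the ratio of libraries, in which length cancels, still varied by an SD of at least 0.495 over 10718 genes.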
